A study of Homo sapiens with 63 samples.

How the data were processed

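RNA from 63 samples of COLO320DM, a human colorectal adenocarcinoma line, had been sequenced after poly(A) enrichment of stranded libraries. The labels place the libraries in 21 groups of 3 replicates. The groups are DMSO (the solvent control), Helicon 4 at 1, 3 or 10 µM and Helicon 4-neg at 1, 3 or 10 µM, each at 6, 24 and 48 h. Whether the replicates were separate cultures is not stated, so the p-values measure only the spread between these samples. Replicate numbers did not pair libraries: the mean residual correlation of libraries with the same number was -0.0513, -0.0218 and -0.0471 at 6, 24 and 48 h. The 63 pairs of replicates included 0 identical columns, and their chi-square per gene between replicates ran from 1.94 to 29.6.

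The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.7a, featureCounts, Subread 2.4.2, edgeR 4.0.2 and the genome build GRCh38. The annotation, the use of the strand in counting and the gene filter are not given. The deposited table holds 1 value per gene and library for 13962 genes, 14 of which share a symbol with another gene, and the unit of these values was taken as signal, the normalised value as the authors deposited it. Each column behaved as CPM divided by a scaling factor. Column sums ran from 0.930 to 1.06 times their geometric mean, and 100% of the values in every library were whole multiples of 1 read within a tolerance of 0.01 read. The value of 1 read, from 0.0301 to 0.0622, gave back whole reads. These summed to 16628595 to 32860333 reads per library, with a median of 22123187, over the genes in the table. PCR copies cannot be told from molecules here, so read totals describe counting error only. Of the gene identifiers, 13952 were found in GENCODE 29, which supplied coordinates and the exons for GC content; gene lengths came with the table.

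For each time, limma 3.58.1 in R 4.3.3 (trend, without the robust option) was fitted to log2(value + 1) of the 21 libraries with 1 coefficient per group. Genes with a value of at least 0.5 in at least 3 libraries were kept: 13057 at 6 h, 13213 at 24 h and 13478 at 48 h. The added 1 shrinks fold changes of genes with low values. Contrasts were Helicon 4 against DMSO, Helicon 4-neg against DMSO and Helicon 4 against Helicon 4-neg at each dose and time, and the slope of each compound per 10-fold dose. Differences between times were tested in 1 fit of all 63 libraries and 13782 genes. P-values were two-sided and adjusted by Benjamini and Hochberg within a contrast, a gene was called below an adjusted p of 0.05, and no fold threshold was applied. Errors given after ± are standard deviations (SD) of 3 libraries, and SE is the standard error of a log2 fold change. Intervals of a difference are 95% intervals from the same fit.

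The 29 gene lists were fixed from textbook knowledge before the data were examined, as were the contrasts, the tests, the rule for named genes and the alternatives except those named below as later. They hold Wnt target genes, Wnt feedback regulators, Wnt pathway components, MYC-responsive genes, the MYC locus, intestinal differentiation, neuroendocrine genes, stem and progenitor genes, S phase, G2/M phase, p53 targets, apoptosis and cell death, ATF4 and the integrated stress response, the unfolded protein response, heat shock, cholesterol synthesis, lysosome, NRF2, hypoxia and glycolysis, NF-kappaB, interferon, immediate-early genes, Notch, BMP and Hippo targets, ribosomal proteins, mitochondrially encoded transcripts, replication-dependent histones, and markers of fibroblasts, leukocytes and other epithelial lines. A list with at least 3 measured members was tested with camera (preset correlation 0.01, adjusted over the lists of a contrast), and again with an estimated correlation and with fry. The counts of members were adjusted over all genes tested and also adjusted over the list alone.

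Named genes followed a rule. It took each measured Wnt feedback regulator with MYC, CTNNB1, TCF7L2, LGR5, ASCL2 and CCND1 at 10 µM, and the doses of AXIN2 and NKD1. It also took the 8 largest rises and 8 largest falls of each Helicon 4 10 µM contrast with DMSO, and 4 and 4 for the other contrasts at 10 µM. These came from called genes with a mean log2 value of at least 3 whose 3 treated values all lay beyond all 3 comparison values. For each called list the rule took the 4 members with the smallest p, and the text names some of these. Identifiers without a gene symbol were skipped.

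Alternatives were robust empirical Bayes, median centring per library, no filter on low values, a pseudocount of 0.1, 1 fit of all 63 libraries, the replicate number as a block, and leaving out each library in turn. Chosen after the data had been seen were edgeR 4.0.16 (quasi-likelihood) on the recovered reads, a model term for the position of a library in the label order, removal of each library's trend on gene length and GC content (for counts, and for the named genes of Helicon 4-neg 10 µM against DMSO at 24 h), leaving out libraries for the differences between times, and all alternatives for single genes in those differences. Other splits of the samples were counted, at most 100 per result. The pipeline was tested on simulated data made from these libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

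Isoforms were not resolved. The use of the strand is not given, so reads of overlapping antisense genes could not be separated. Values of near-identical copies, such as the HIST1 histone genes, HSPA1A and HSPA1B, and POU5F1B beside MYC, depend on how shared reads were assigned, which is not given. Gene length was not corrected for, so levels of different genes were not compared with one another. Raw reads were not analysed here.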

Results

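COLO320DM, a human colorectal adenocarcinoma line grown in culture, was treated with Helicon 4, which the series title describes as a helicon peptide aimed at β-catenin/TCF, the transcription complex at the end of the Wnt pathway. Helicon 4-neg is the companion compound in the labels, and DMSO is the solvent control. Messenger RNA was measured in 63 libraries, 3 in each of 21 groups: DMSO and 1, 3 and 10 µM of each compound at 6, 24 and 48 h. The libraries held 16628595 to 32860333 reads in the genes listed, so that 1 read was worth 0.0301 to 0.0622 in scaled CPM, the unit of all levels given here. Coordinates refer to GRCh38.

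The comparison of Helicon 4 with DMSO at the same time asked which genes the compound changed. At 6 h and 10 µM, genes that restrain Wnt signalling and are themselves switched on by it fell together. AXIN2, a scaffold of the β-catenin destruction complex (ENSG00000168646, chromosome 17, 65528563 to 65561647), had a level of 188 ± 8.1 with DMSO and 65.6 ± 3.9 with Helicon 4 (SD, n = 3). Its log2 fold change was -1.50 (SE 0.045, limma adjusted p = 7e-18). TNFRSF19, a receptor of the tumour necrosis factor family (ENSG00000127863, chromosome 13, 23570370 to 23676104), went from 85.1 ± 1.2 to 22.1 ± 1 (log2 fold change -1.90, SE 0.047, adjusted p = 3.7e-19). APCDD1, a membrane-bound Wnt inhibitor (ENSG00000154856, chromosome 18, 10454628 to 10489948), went from 485 ± 18 to 177 ± 9.9 (log2 fold change -1.45, SE 0.039, adjusted p = 1.2e-18). NKD1, an inhibitor that binds Dishevelled (ENSG00000140807, chromosome 16, 50548330 to 50649249), fell by 1.51 on the log2 scale (adjusted p = 1.8e-14), from 40 ± 2.8 to 13.4 ± 0.55. All 11 measured feedback regulators fell, 11 also when adjusted over the list alone, with a median log2 fold change of -1.39 (camera adjusted p = 9.4e-30, and adjusted p = 3.8e-05 with an estimated correlation). The others at 6 h were DKK1 at -2.16, SP5 at -1.39, RNF43 at -1.07, ZNRF3 at -0.59, NOTUM at -0.38, WIF1 at -0.31 and KREMEN1 at -0.19. The call of KREMEN1 was lost without Helicon 4 10 µM replicate 2 (-0.16) and without DMSO replicate 2 (-0.13).

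At later times the same regulators other than KREMEN1 lay below DMSO, with some further below it than at 6 h. NOTUM, a secreted enzyme that inactivates Wnt proteins (ENSG00000185269, chromosome 17, 81952507 to 81961840), had log2 fold changes of -2.22 (SE 0.065, adjusted p = 2.2e-16) at 24 h and -2.85 (SE 0.062, adjusted p = 1.5e-20) at 48 h, where its level was 89.1 ± 4.8 with DMSO and 11.5 ± 0.59 with Helicon 4 (SD, n = 3). WIF1, a secreted Wnt-binding inhibitor (ENSG00000156076, chromosome 12, 65050626 to 65121566), had -2.86 at 24 h and -3.39 at 48 h, with levels of 32.7 ± 2.3 and 2.23 ± 0.4 at 48 h. AXIN2 had -1.48 and -1.70, NKD1 -1.73 and -1.69, APCDD1 -2.07 and -2.68, and TNFRSF19 -2.51 and -3.02 at 24 and 48 h. Over the same times RNF43 had -0.85 and -1.05, ZNRF3 -0.71 and -0.67, DKK1 -1.68 and -2.53, and SP5 -1.67 and -2.15. KREMEN1, a co-receptor of DKK1, rose by 0.22 (adjusted p = 0.0039) and 0.25 (adjusted p = 2e-04). At 24 h 10 of 11 regulators fell and 1 rose, 10 and 1 also adjusted over the list alone, with a median of -1.68 (camera adjusted p = 1.5e-09, and adjusted p = 0.0016 with an estimated correlation). At 48 h 11 of 12 fell and 1 rose, 11 and 1 also adjusted over the list alone, with a median of -1.93 (camera adjusted p = 3e-09, and adjusted p = 0.00031 with an estimated correlation). DKK4 was listed at 0 in all 3 Helicon 4 libraries at 48 h, beside 0.313 ± 0.048 with DMSO, and its place anywhere between -0.39 and 0 leaves that median as it is.

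Genes around β-catenin moved in more than 1 direction. CTNNB1, the gene of β-catenin (ENSG00000168036, chromosome 3, 41194741 to 41260096), rose by 0.31, 0.46 and 0.54 at 6, 24 and 48 h (adjusted p = 2.7e-07, 8.4e-11 and 1.3e-08). MYC, a growth-promoting transcription factor (ENSG00000136997, chromosome 8, 127735434 to 127741434), had 3820 ± 210 with DMSO and 3170 ± 120 with Helicon 4 at 6 h, a fall of -0.27 (adjusted p = 0.00011). It fell by 0.19 at 24 h (adjusted p = 0.0049) and rose by 0.32 at 48 h (adjusted p = 1.2e-05), from 2640 ± 160 to 3280 ± 88. ASCL2, a transcription factor of intestinal stem cells, had -0.54, -1.16 and -2.10, and CCND1, the gene of cyclin D1, had -0.27, -0.62 and -0.79, each with an adjusted p below the threshold. The 6 h call of CCND1 was lost without DMSO replicate 2 (-0.19). LGR5, a stem cell receptor, did not pass at any of the 3 times (-0.01, -0.19 and -0.03, adjusted p = 0.96, 0.25 and 0.87). TCF7L2, which encodes a DNA-binding partner of β-catenin, had -0.25, 0.40 and 0.19 (adjusted p = 0.22, 0.077 and 0.17). At 24 h TCF7L2 passed without Helicon 4 10 µM replicate 2 (0.63), in 1 fit of all 63 libraries (0.40), with edgeR (0.52) and with the library-order term (0.48).

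**Figure D1:**
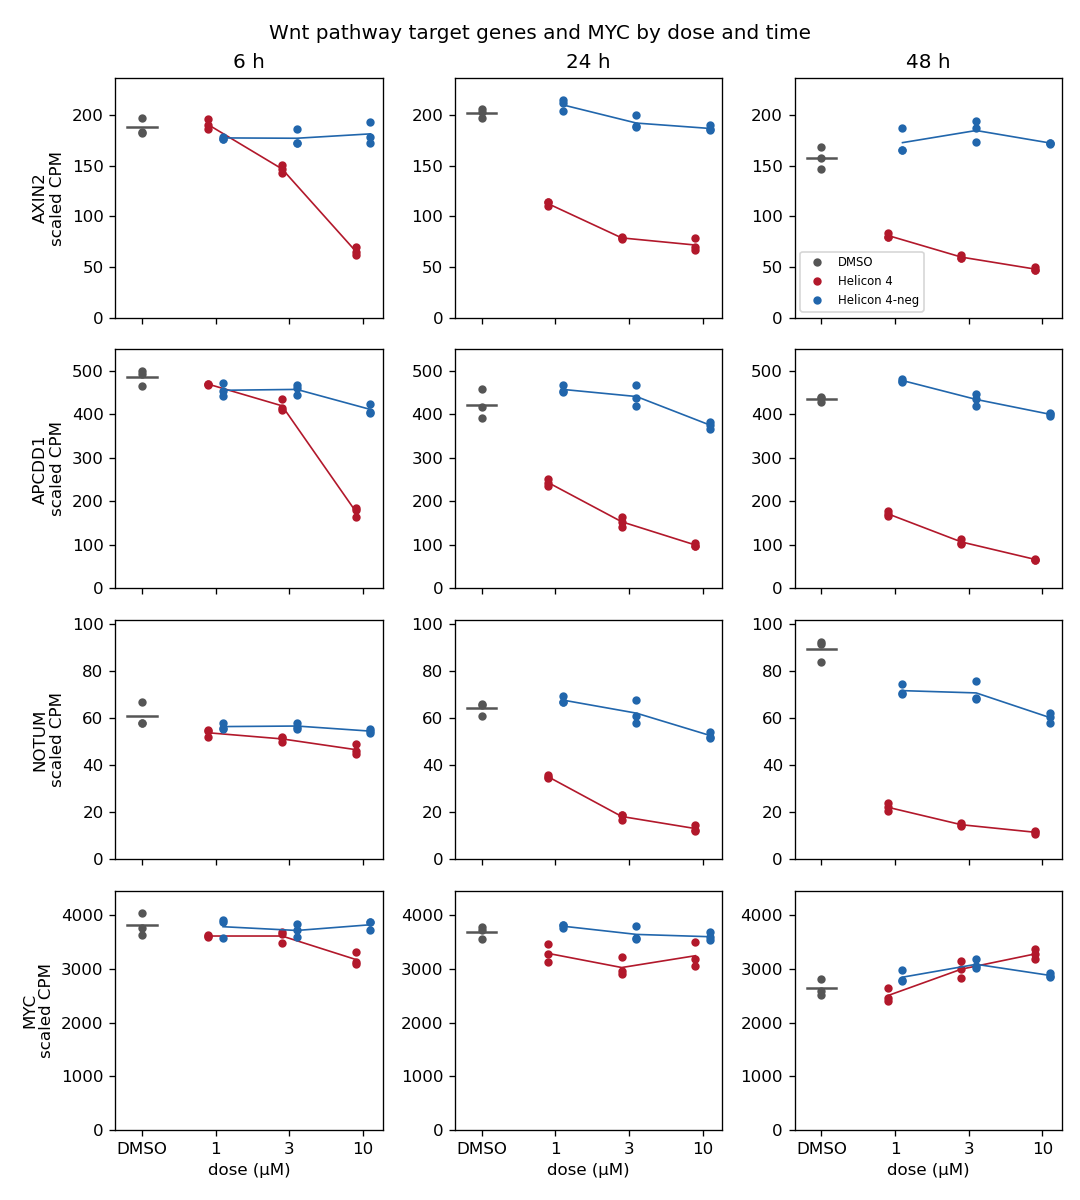
Levels of AXIN2, APCDD1, NOTUM and MYC (vertical axes, scaled CPM) against dose in µM (horizontal axes, DMSO at the left) at 6, 24 and 48 h, where each point is 1 library, lines join the means of 3 libraries and the grey bar is the DMSO mean. AXIN2 at 48 h averaged 158 with DMSO, 48 with 10 µM Helicon 4 and 173 with 10 µM Helicon 4-neg.

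The wider list of Wnt target genes, switched on by β-catenin/TCF in intestinal cells, fell as a group at 6 and 48 h, and at 24 h with the preset correlation only. It includes all the feedback regulators above, so its result is not separate from theirs. At 6 h 26 of 42 members fell and 1 rose, 28 and 1 adjusted over the list alone, with a median of -0.39 (adjusted p = 4.9e-24, and adjusted p = 0.00092 with an estimated correlation). At 24 h 23 of 43 fell and 7 rose, 23 and 8 adjusted over the list alone (median -0.62, adjusted p = 0.00014, and adjusted p = 0.096 with an estimated correlation). At 48 h 23 of 44 fell and 12 rose (median -0.38, adjusted p = 0.001, and adjusted p = 0.027 with an estimated correlation). The feedback regulators gave 11 of these falls and 1 of the rises, and the other members were not tested alone. Members that rose at 48 h, named after their values were seen, included ISX, a homeobox gene of the intestine, and EPHB3, an ephrin receptor. ISX went from 0.0587 ± 0.063 to 14.8 ± 0.2 (log2 fold change 3.90, SE 0.12), and EPHB3 from 7.01 ± 0.74 to 37.3 ± 2.4 (log2 fold change 2.26, SE 0.098). Stem and progenitor genes overlap this list: 6, 8 and 8 of 16 fell and 2, 2 and 5 rose at 6, 24 and 48 h. Their adjusted p was 1.8e-05, 0.0036 and 0.022, and adjusted p = 0.0032, 0.042 and 0.062 with an estimated correlation. AXIN2, RNF43 and TNFRSF19 were among the 4 members with the smallest p at each time.

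Beyond the Wnt genes, the largest changes at 6 h and 10 µM were smaller rises and deeper falls. ID3, an inhibitor of helix-loop-helix factors that BMP signalling induces, rose by 0.80 (SE 0.066, adjusted p = 3.5e-09), from 61.7 ± 3.9 to 108 ± 3.6 (SD, n = 3). TFEB, a regulator of lysosome genes, rose by 0.79, KCNJ15 by 0.77, INHBB by 0.71, the cochaperone gene DNAJB1 by 0.69, CCNG2 by 0.68, SERTAD1 by 0.63 and the stress-induced ATF3 by 0.61. IRX5, a homeobox gene, fell by 1.86 (SE 0.055, adjusted p = 7e-18), MEDAG by 1.73, OXR1 by 1.66 and ERN1, a sensor of misfolded protein, by 1.39. All 3 treated values lay beyond all 3 DMSO values for each of these genes, as the rule for naming them required.

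By 24 and 48 h other genes led. BMF, which encodes a pro-apoptotic BCL2-family protein (ENSG00000104081, chromosome 15, 40087890 to 40108892), went from 4.89 ± 0.79 to 44.6 ± 2.9 at 24 h and from 4.6 ± 0.42 to 65.7 ± 1 at 48 h (log2 fold changes 2.96, SE 0.1, and 3.58, SE 0.091, adjusted p = 2.1e-15 and 3.5e-19). HDC, the gene of the enzyme that makes histamine (ENSG00000140287, chromosome 15, 50241947 to 50266026), went from 153 ± 3 to 17 ± 0.15 at 24 h and from 166 ± 9.1 to 12.3 ± 1.5 at 48 h (log2 fold changes -3.10, SE 0.048, and -3.66, SE 0.058, adjusted p = 5.5e-21 and 4.8e-23). TMSB4X, which encodes the actin-binding thymosin beta 4, rose by 2.09 and 3.16, and reached 365 ± 13 at 48 h beside 40 ± 4.7 with DMSO. EDIL3 rose by 2.83 and 3.05, TMCC3 by 2.44 and 3.09, and HIST1H2AC by 2.59 and 3.54 at 24 and 48 h. At 24 h TP53INP2 rose by 2.92, SEMA3A by 2.22 and DYRK1B by 2.04, while PRSS23 fell by 2.48 and C9orf3 by 2.28, and COL13A1 fell as well (SE 0.1, adjusted p = 5.9e-14). At 48 h CTNNA2 rose by 3.27, RGS2 by 3.03 and TNMD by 2.81, while the meprin gene MEP1B fell by 3.28, the keratin gene KRT39 by 2.89, C9orf3 by 2.77 and FARS2 by 2.77.

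At 6 h and 10 µM, several stress and metabolic lists rose slightly. Cholesterol synthesis genes rose in 17 of 24 members and fell in 1 (19 and 1 adjusted over the list alone, median 0.20, adjusted p = 4e-14, and adjusted p = 0.002 with an estimated correlation). Members included HMGCS1 at 0.42 and FDFT1 at 0.33. Of the heat shock genes 8 of 14 rose (12 adjusted over the list alone, adjusted p = 2.4e-11, and adjusted p = 0.0037 with an estimated correlation). Members included HSPA1B at 0.52 and HSPH1 at 0.36. Of the ATF4 genes 6 of 23 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 8.8e-05, and adjusted p = 0.0037 with an estimated correlation). Members included DDIT4 at 0.51. Of the S phase genes 9 of 30 rose and 1 fell (14 and 2 adjusted over the list alone, adjusted p = 6.2e-05, and adjusted p = 0.0035 with an estimated correlation). Members included RRM2 at 0.27 and UNG at 0.21; 17 and 0 passed after median centring. NRF2 genes rose in 4 of 14 members, 8 adjusted over the list alone (adjusted p = 9e-04, and adjusted p = 0.018 with an estimated correlation).

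Other 6 h lists passed with the preset correlation alone. G2/M genes rose in 6 of 32 members, with 7 up and 1 down adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.14 with an estimated correlation). Lysosome genes rose in 6 of 25 and fell in 1, 7 and 1 adjusted over the list alone (adjusted p = 0.031, and adjusted p = 0.14 with an estimated correlation). Members included ATP6V1A at 0.37. At the MYC locus 2 of 7 fell, MYC and CCAT2, a noncoding RNA (log2 fold change -0.90, SE 0.083); the list had adjusted p = 0.029, and adjusted p = 0.069 with an estimated correlation. No ribosomal protein gene of 30 was called at 6 h by limma, while the list had a median of 0.07 (adjusted p = 0.002, and adjusted p = 0.74 with an estimated correlation). Of the 13 mitochondrially encoded transcripts, read as a sign of RNA quality and cell state, 11 fell (13 adjusted over the list alone, median -0.34, adjusted p = 4.8e-08, and adjusted p = 0.17 with an estimated correlation).

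By 24 h genes of DNA replication and ribosome assembly had fallen. All 30 S phase genes fell, 30 also adjusted over the list alone (median -0.72, adjusted p = 5.9e-20, and adjusted p = 0.0014 with an estimated correlation). Members included the helicase genes MCM4 at -1.01 (SE 0.039), MCM3 at -0.89 and MCM2 at -0.67. MYC-responsive nucleolar and nucleotide synthesis genes fell in 30 of 32 members (30, with 1 rise, adjusted over the list alone; median -0.54, adjusted p = 6.6e-13, and adjusted p = 0.0014 with an estimated correlation). Members included RRP9 at -0.78 and GNL3 at -0.70. All 8 measured histone genes of the replication-dependent class rose (median 1.13, adjusted p = 3.2e-06, and adjusted p = 0.0014 with an estimated correlation), among them HIST1H2BD at 1.90 and HIST1H1C at 1.17. Transcripts of this class mostly lack poly(A), and the libraries were enriched for it. Here and below, the values therefore cover mainly their polyadenylated part, and total histone RNA was not measured. Lysosome genes rose in 17 of 25 members, 18 adjusted over the list alone (median 0.24, adjusted p = 2.7e-06, and adjusted p = 0.049 with an estimated correlation). Members included ATP6V1A at 1.12 and NEU1 at 1.01. With the preset correlation alone, G2/M genes fell in 20 of 32 (adjusted p = 0.00095, and adjusted p = 0.074 with an estimated correlation), unfolded protein response genes in 13 of 17, with 1 rise (adjusted p = 0.00012, and adjusted p = 0.074 with an estimated correlation), and cholesterol synthesis genes in 20 of 24, with 1 rise (adjusted p = 5e-06, and adjusted p = 0.1 with an estimated correlation). SQLE fell by 0.75, DHCR7 by 0.53 and LSS by 0.55, while TM7SF2 rose by 0.75. Ribosomal protein genes rose in 17 of 30, 19 adjusted over the list alone (median 0.16, adjusted p = 0.00095, and adjusted p = 0.81 with an estimated correlation). All 13 mitochondrially encoded transcripts were higher, opposite to 6 h (median 0.36, adjusted p = 0.00096, and adjusted p = 0.61 with an estimated correlation).

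At 48 h mitotic genes lay below DMSO. G2/M genes fell in 30 of 32 members (median -0.58, adjusted p = 8.3e-14, and adjusted p = 0.0017 with an estimated correlation). Members included the kinase genes AURKB at -0.99 and AURKA at -0.65, and TPX2 at -0.80. S phase genes fell in 28 of 30 (median -0.77, adjusted p = 4.8e-17, and adjusted p = 0.0038 with an estimated correlation). Members included RRM2 at -1.09 and MCM3 at -0.93. MYC-responsive genes fell in 27 of 32 and 1 rose (29 and 1 adjusted over the list alone, median -0.41, adjusted p = 3.7e-09, and adjusted p = 0.00052 with an estimated correlation), while MYC itself was higher. Unfolded protein response genes fell in 13 of 17 and 2 rose (median -0.53, adjusted p = 8.4e-06, and adjusted p = 0.0078 with an estimated correlation). Members included PDIA4 at -1.24 and HSPA5 at -0.62. Cholesterol synthesis genes fell in 21 of 24 and 2 rose (21 and 3 adjusted over the list alone, median -0.60, adjusted p = 2.6e-08, and adjusted p = 0.044 with an estimated correlation). Members included EBP at -0.93. Lysosome genes rose in 16 of 25 and 2 fell (median 0.32, adjusted p = 0.001, and adjusted p = 0.012 with an estimated correlation). Members included GABARAPL1 at 1.07 and SQSTM1 at 0.90. All 9 histone genes rose (median 1.57, adjusted p = 1.1e-05, and adjusted p = 0.0089 with an estimated correlation), and HIST1H2AC went from 4.21 ± 0.63 to 59.4 ± 4.1 (SD, n = 3).

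Besides the stem and progenitor genes given above, lists that passed at 48 h with the preset correlation alone were heat shock, Wnt components and ribosomal proteins. Heat shock genes rose in 9 of 15 and fell in 2 (median 0.25, adjusted p = 0.022, and adjusted p = 0.16 with an estimated correlation). Members included CRYAB at 1.08 and HSPB1 at 0.76. Wnt components rose in 11 of 18 and 1 fell (median 0.22, adjusted p = 0.043, and adjusted p = 0.36 with an estimated correlation). Members included FZD5 at 0.79 and APC at 0.79. Ribosomal protein genes fell in 18 of 30 and 2 rose (median -0.19, adjusted p = 0.0056, and adjusted p = 0.75 with an estimated correlation). Not called at 48 h were p53 targets (7 of 20 rose, 4 fell, adjusted p = 0.37), apoptosis genes (7 of 19 rose, 5 fell, adjusted p = 0.94), ATF4 genes (6 of 24 rose, 13 fell, adjusted p = 0.06), hypoxia and glycolysis (6 of 22 rose, 9 fell, with 7 and 9 adjusted over the list alone, adjusted p = 0.94), neuroendocrine genes (2 of 16 rose, 2 fell, adjusted p = 0.99) and intestinal differentiation (1 of 9 rose, 3 fell, adjusted p = 0.17). The NRF2 list (6 of 14 rose, 4 fell, adjusted p = 0.94) had a median of -0.05 and a mean of 0.08. The hypoxia list had a median of 0.04 and a mean of 0.16 while its test pointed down, and the MYC locus (4 of 7 rose, 3 fell, adjusted p = 0.94) had a median of 0.30 and a mean of -0.21. Immediate-early genes (8 of 21 rose, 6 fell, adjusted p = 0.88), Notch, BMP and Hippo targets (6 of 16 rose, 4 fell, adjusted p = 0.79) and mitochondrially encoded transcripts (6 of 13 fell, median -0.58, adjusted p = 0.091) did not pass either.

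NF-kappaB and interferon genes differed between libraries by their place in the label order, whatever the treatment. Libraries alternated in pairs along the label order. CXCL10, a chemokine that interferon induces, was at 24.1 to 47.2 in 31 libraries and at 0 to 0.426 in 32. GFAP, an astrocyte filament, was at 2.53 to 4.92 in the 31 and 20.2 to 36.7 in the 32. In all, 690 of 13782 genes differed between these libraries in limma, 423 higher and 267 lower in the 31, among them 18 of 20 interferon, 10 of 15 NF-kappaB and 7 of 8 fibroblast genes. Each of the 21 groups held both kinds. Helicon 4 10 µM had 1, 2 and 2 of the 31 at 6, 24 and 48 h, and DMSO 2, 1 and 1. Under Helicon 4 10 µM at 48 h, interferon genes rose in 7 of 20 (adjusted p = 0.06). NF-kappaB genes rose in 4 of 15 with 1 fall (adjusted p = 0.15), and fibroblast markers in 1 of 8 (adjusted p = 0.79). None was called, and this imbalance itself raises all 3. RELB, an NF-kappaB subunit gene named after its values were seen, rose by 1.40 (SE 0.11). Markers of other epithelial lines (1 of 3 rose, median -0.09, mean 0.47, adjusted p = 0.69) did not pass at 48 h, and leukocyte markers, with 2 measured, were not tested. Of the Wnt feedback regulators 1 of 12 differed between the 31 and the 32 libraries, and the median of these 12, which include DKK4 at each time, under Helicon 4 10 µM was -1.21 within each set at 6 h, -1.64 and -1.60 at 24 h, and -1.88 and -1.94 at 48 h.

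**Figure D2:**
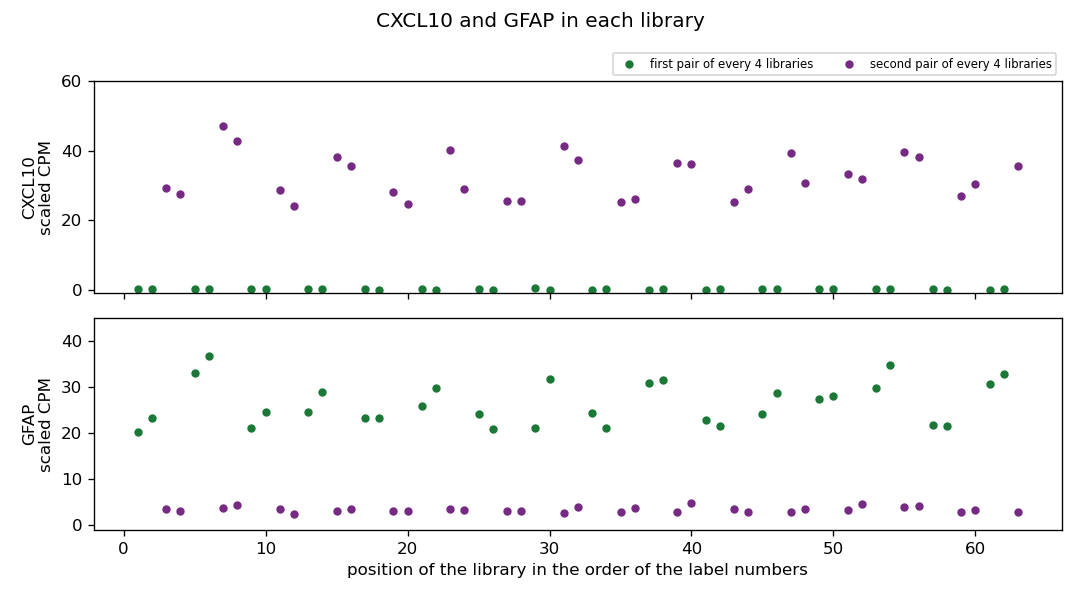
CXCL10 and GFAP in scaled CPM (vertical axes) against the position of each library in the order of the label numbers (horizontal axis), where each point is 1 of 63 libraries, green for the first and purple for the second pair of every 4. CXCL10 lay at 24.1 to 47.2 in the 31 purple and 0 to 0.426 in the 32 green libraries. GFAP lay at 2.53 to 4.92 and 20.2 to 36.7.

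The number of genes called for Helicon 4 against DMSO was larger at 24 and 48 h than at 6 h. At 10 µM limma called 694 genes higher and 1097 lower at 6 h, 3323 and 3645 at 24 h, and 4196 and 3865 at 48 h, with changes of at least 2-fold in 39, 396 and 757. At 3 µM the counts were 607 and 590, 2744 and 3226, and 4147 and 3836, and at 1 µM they were 732 and 923, 1135 and 1366, and 2656 and 2857. Median centring per library turned the balance at 6 h, to 1163 higher and 732 lower at 1 µM, 888 and 430 at 3 µM, and 1370 and 766 at 10 µM. Single libraries mattered at 6 h. The 1655 calls at 1 µM became 530 without Helicon 4 replicate 1, 301 without its replicate 2 and 209 without DMSO replicate 2. Those at 3 µM, 1197 in all, became 446 and 767 without Helicon 4 replicates 2 and 3, and 582 without DMSO replicate 2, and the 1791 at 10 µM became 1170 without DMSO replicate 2. At 24 h the 2501 calls at 1 µM became 1605 and 1637 without Helicon 4 replicates 1 and 3. DMSO 6 h replicate 2 stood apart from replicates 1 and 3 (chi-square per gene 8.39 and 11.9, beside 2.58 between those). At 24 h replicate 1 stood apart with Helicon 4 10 µM (17.3 and 11.3, beside 3.45) and 3 µM (8.50 and 13.2), without moving a count by over 1.5 times. With each library's trend on gene length and GC content removed, 950 genes were called at 1 µM and 6 h, and a fit of all 63 libraries called 831.

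**Figure D3:**
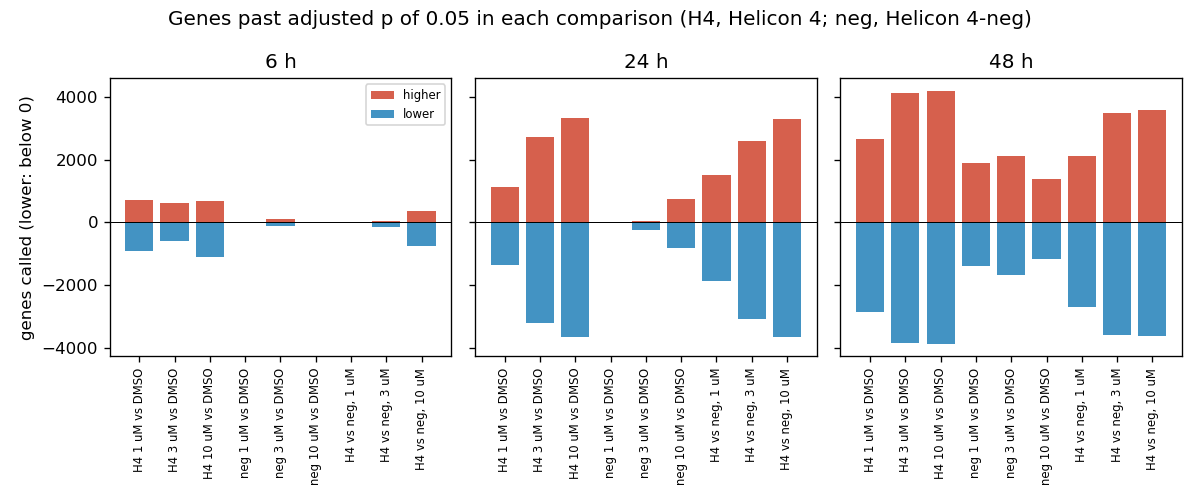
Genes called in each comparison (vertical axis, number of genes, higher above 0 and lower below) for the 9 comparisons named on the horizontal axis at 6, 24 and 48 h, where each bar is 1 limma contrast. Helicon 4 10 µM against DMSO gave 694 higher and 1097 lower at 6 h and 4196 and 3865 at 48 h, and the balance at 6 h turned to 1370 and 766 after median centring.

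AXIN2 fell with the dose of Helicon 4 at each time. Its log2 fold change against DMSO was 0.02 at 1 µM (adjusted p = 0.81), -0.35 at 3 µM (adjusted p = 4.1e-05) and -1.50 at 10 µM, while at 24 h it was -0.84, -1.35 and -1.48, and at 48 h -0.95, -1.38 and -1.70. Per 10-fold dose of Helicon 4 the AXIN2 slope was -1.54 at 6 h (adjusted p = 4.3e-18), -0.64 at 24 h (adjusted p = 8.4e-10) and -0.75 at 48 h (adjusted p = 2.9e-10). NKD1 had -0.22 (adjusted p = 0.032), -0.73 and -1.51 at 6 h, -1.63, -1.91 and -1.73 at 24 h, and -1.94, -1.90 and -1.69 at 48 h, with slopes of -1.29 (adjusted p = 3.9e-13), -0.09 (adjusted p = 0.49) and 0.25 (adjusted p = 0.0077). The 1 µM call of NKD1 at 6 h was lost without Helicon 4 replicate 1 (-0.16) or 2 (-0.23), without DMSO replicate 2 (-0.16) and in 1 fit of all 63 libraries (-0.22), and its 48 h slope without Helicon 4 10 µM replicate 2 (0.20). For Helicon 4-neg the AXIN2 slopes were 0.03 (adjusted p = 0.94), -0.17 (adjusted p = 0.017) and -0.01 (adjusted p = 0.98). The 24 h slope was lost without Helicon 4-neg 10 µM replicate 1 (-0.16) or 3 (-0.16), without Helicon 4-neg 1 µM replicate 1 (-0.15) or 3 (-0.16) and after centring (-0.10). Across all genes the slope of Helicon 4 was called for 450 up and 684 down at 6 h, 2068 and 2669 at 24 h, and 2178 and 2035 at 48 h; after centring these were 530 and 536 at 6 h and 1681 and 2723 at 48 h. The 1134 calls at 6 h became 689 without Helicon 4 10 µM replicate 1.

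The slope of Helicon 4-neg at 6 h was called for 8 genes, named here after their values were seen: ID3 (-0.68 per 10-fold dose), SMAD9 (-0.65), MSX2 (-0.65), PRSS23 (-0.31), ALAS1 (-0.26) and LIMS1 (-0.18) fell, and UST (0.32) and GPT2 (0.20) rose. ID3, SMAD9 and MSX2 are targets of BMP signalling. The count became 3 without the 10 µM replicate 2, 4 without the 1 µM replicate 1 and 3 without the 1 µM replicate 2. At 24 h 1304 genes rose and 1308 fell with dose, 2130 and 793 after centring. The total of 2612 became 1029, 1473 and 1707 without the 10 µM replicates 1, 2 and 3, and 852, 1732 and 1565 without the 1 µM replicates 1, 2 and 3. At 48 h 153 rose and 149 fell. The total of 302 became 109, 72 and 126 without the 10 µM replicates 1, 2 and 3, and 93 and 128 without the 1 µM replicates 2 and 3; it was 944 with the library-order term.

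Whether the effect of Helicon 4 10 µM differed between times was tested directly. The effect on HDC at 48 h differed from that at 6 h by -3.70 on the log2 scale (SE 0.076, adjusted p = 8.3e-40), and that on BMF by 2.49 (SE 0.14, adjusted p = 2.4e-21). WIF1 differed by -3.08 (SE 0.12, adjusted p = 7.6e-27) and NOTUM by -2.47 (SE 0.083, adjusted p = 2.9e-30). MYC differed by 0.58 (SE 0.07, adjusted p = 6.5e-10), since it fell at 6 h and rose at 48 h. RNF43 (0.02, adjusted p = 0.86), ZNRF3 (-0.09, adjusted p = 0.58), DKK1 (-0.37, adjusted p = 0.31) and NKD1 (-0.18, adjusted p = 0.17) did not pass, and NKD1 passed after centring (-0.30). Of 13782 genes, 2614 differed upward and 2703 downward between 24 and 6 h, 3688 and 3114 between 48 and 6 h, and 2700 and 2020 between 48 and 24 h. After centring the last 2 splits were 2624 and 4148, and 1864 and 2686. The difference between the compounds changed from 6 to 48 h for 2855 genes upward and 2744 downward, with AXIN2 at -0.37 (SE 0.07, adjusted p = 1.7e-05).

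The comparison of Helicon 4-neg with DMSO asked what the companion compound changed. ID3 and ID2, which BMP signalling induces, fell. ID3 (ENSG00000117318, chromosome 1, 23557918 to 23559794) went from 61.7 ± 3.9 with DMSO to 40.4 ± 1.9 at 6 h and from 54.2 ± 2.7 to 24.1 ± 1.5 at 48 h (log2 fold changes -0.60, SE 0.066, and -1.14, SE 0.052, adjusted p = 4.3e-05 and 8.2e-13), while Helicon 4 raised it at 6 h. SMAD9, a BMP signal transducer, fell by 0.63 at 6 h (adjusted p = 0.00031) and ID2 by 0.85 at 48 h (adjusted p = 1.1e-05). SLC7A11, a cystine transporter gene, rose by 0.56 at 6 h (adjusted p = 0.003), BTG2, an antiproliferative gene, by 0.50 at 24 h and 0.93 at 48 h (adjusted p = 0.0014 and 4e-06), and COTL1 by 0.47 at 24 h (adjusted p = 2.3e-07). At 24 h TM7SF2 rose by 0.44 and TMEM205 by 0.42. At 48 h RSRP1 fell by 1.39 (SE 0.061, adjusted p = 5.6e-13), from 42.8 ± 1.3 to 15.7 ± 1, RRBP1 fell by 0.77, and IGF2BP3 rose by 0.80 and TBC1D14 by 0.69. CYP51A1 rose by 0.81 at 48 h, a call lost without Helicon 4-neg replicate 2 (0.81) or 3 (0.81), without DMSO replicate 2 (0.81) or 3 (0.68), and with robust empirical Bayes (0.81). At 24 h the mitotic gene CENPF had -1.30 (SE 0.28, adjusted p = 0.0074), APC -1.05 (SE 0.197), CCDC88A -0.97 (SE 0.174) and TPR -1.05 (SE 0.256), the last lost without Helicon 4-neg replicate 1 (-1.02) or DMSO replicate 1 (-1.01). These 4 transcripts are long, 11690 bases for CENPF, 12440 for APC, 14537 for CCDC88A and 12350 for TPR, longer than 93.4, 94.9, 97.3 and 94.7% of the genes tested. In this contrast fold change and length had a Spearman correlation of -0.40 across genes, which are not independent, so that long transcripts were lower in general. With each library's trend on length and GC content removed, a correction tried on these genes after that was seen, the values were -1.19, -0.92, -0.82 and -0.93 (adjusted p = 0.0089, 0.0041, 0.0033 and 0.018).

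Calls of smaller changes at 6 h with Helicon 4-neg 10 µM were lost when libraries were left out, while the fold changes moved little. PNRC1 fell by 0.42, lost without Helicon 4-neg replicate 1 (-0.40). GRAMD1A fell by 0.38, lost without Helicon 4-neg replicate 1 (-0.39), 2 (-0.36) or 3 (-0.38) and without DMSO replicate 2 (-0.32). PLCL1 rose by 0.35, lost without Helicon 4-neg replicate 1 (0.32), 2 (0.37) or 3 (0.38) and without DMSO replicate 1 (0.31) or 2 (0.35). VCL rose by 0.27, lost without Helicon 4-neg replicate 1 (0.26), 2 (0.25) or 3 (0.29) and without DMSO replicate 1 (0.26) or 3 (0.22). SLC39A14 rose by 0.24, lost without Helicon 4-neg replicate 1 (0.26), 2 (0.22) or 3 (0.24) and without DMSO replicate 2 (0.23) or 3 (0.21).

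Most Wnt feedback regulators stayed near DMSO under Helicon 4-neg 10 µM, while some, such as NOTUM, fell. AXIN2 had log2 fold changes of -0.05, -0.11 and 0.13 at 6, 24 and 48 h (adjusted p = 0.74, 0.12 and 0.093), and NKD1 had -0.15, 0 and 0.03. The 48 h value of AXIN2 passed without DMSO replicate 1 (0.18) and in 1 fit of all 63 libraries (0.13), and AXIN2 passed at 3 µM and 48 h (0.23, adjusted p = 0.0035). NOTUM fell by 0.28 at 24 h (adjusted p = 0.01, lost without DMSO replicate 1, -0.26) and by 0.56 at 48 h (adjusted p = 1.2e-05). APCDD1 fell by 0.24 at 6 h (adjusted p = 0.0055), had -0.17 at 24 h (adjusted p = 0.054; passed without DMSO replicate 2, -0.22), and fell by 0.12 at 48 h (adjusted p = 0.033). That last call was lost without Helicon 4-neg replicate 1 (-0.12), 2 (-0.11) or 3 (-0.12) and without DMSO replicate 1 (-0.11), 2 (-0.11) or 3 (-0.13). RNF43 fell by 0.20 at 24 h (adjusted p = 0.025), lost without Helicon 4-neg replicate 1 (-0.18) or 2 (-0.21) and without DMSO replicate 1 (-0.19) or 3 (-0.16). CTNNB1 rose by 0.24 and ASCL2 fell by 0.49 at 48 h (adjusted p = 0.0056 and 0.0054), and MYC had 0.13 at 48 h (adjusted p = 0.079; passed without DMSO replicate 1, 0.18, and with robust empirical Bayes, 0.13). As a list the regulators had a median of -0.08 at 6 h with 1 of 11 lower, 2 adjusted over the list alone (adjusted p = 0.00036, and adjusted p = 0.057 with an estimated correlation), -0.11 at 24 h (adjusted p = 0.088) and 0.03 at 48 h, where the mean was -0.06 (adjusted p = 0.63). The wider Wnt target list did not pass at 24 h (median -0.11, adjusted p = 0.15) or 48 h (median 0.03, adjusted p = 0.83).

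With Helicon 4-neg 10 µM the cholesterol synthesis list was called upward by camera at each time, at 24 and 48 h with the preset correlation alone. None of 24 members was called at 6 h over all genes, 8 rose adjusted over the list alone (median 0.09, adjusted p = 3.5e-10, and adjusted p = 0.011 with an estimated correlation). At 24 h 16 of 24 rose, 19 adjusted over the list alone (median 0.23, adjusted p = 2.7e-13, and adjusted p = 0.073 with an estimated correlation), and at 48 h 17 of 24, 18 adjusted over the list alone (median 0.22, adjusted p = 5.2e-11, and adjusted p = 0.13 with an estimated correlation). DHCR7 rose by 0.35 at 24 h and HMGCS1 by 0.47 at 48 h. ATF4 genes rose in 2 of 23 at 6 h, 7 adjusted over the list alone (adjusted p = 3.1e-06, and adjusted p = 0.0043 with an estimated correlation), and in 5 of 24 at 24 h, 6 adjusted over the list alone (adjusted p = 0.0054, and adjusted p = 0.09 with an estimated correlation). Notch, BMP and Hippo targets fell in 2 of 16 at 6 h, 4 adjusted over the list alone (adjusted p = 0.00029, and adjusted p = 0.05 with an estimated correlation, which does not pass), and in 5 of 16 at 48 h (adjusted p = 0.02, and adjusted p = 0.13 with an estimated correlation). Ribosomal protein genes fell in 21 of 30 at 48 h, 23 adjusted over the list alone (median -0.21, adjusted p = 4.5e-13, and adjusted p = 0.37 with an estimated correlation), after a median of 0.15 at 24 h with 3 of 30 up, 1 adjusted over the list alone (adjusted p = 5e-07, and adjusted p = 0.81 with an estimated correlation). Across all genes tested, fold change and gene length had a Spearman correlation of -0.40 at 24 h and 0.25 at 48 h in these contrasts (GC content 0.11 and -0.29), which also changed sign, and the list was not tested with that trend removed. The mitochondrially encoded transcripts had medians of -0.16 at 6 h, with 3 of 13 down adjusted over the list alone (adjusted p = 4.2e-06, and adjusted p = 0.29 with an estimated correlation) and 0.30 at 24 h, with 7 of 13 up, 10 adjusted over the list alone (adjusted p = 5e-07, and adjusted p = 0.42 with an estimated correlation).

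Of the other lists called upward with Helicon 4-neg at 6 h, heat shock, NRF2 and S phase had also risen with Helicon 4 against the same DMSO libraries. Heat shock genes rose in 1 of 14 (3 adjusted over the list alone, median 0.09, adjusted p = 0.00031, and adjusted p = 0.084 with an estimated correlation), and NRF2 genes in 1 of 14 (2 adjusted over the list alone, median 0.09, adjusted p = 0.0013, and adjusted p = 0.05 with an estimated correlation, which does not pass). No S phase gene of 30 was called over all genes by limma, 4 rose adjusted over the list alone (median 0.03, adjusted p = 0.021, and adjusted p = 0.057 with an estimated correlation). MYC-responsive and unfolded protein response genes had not passed with Helicon 4 at 6 h. With Helicon 4-neg MYC-responsive genes rose in 1 of 32 (median 0.04, adjusted p = 0.0034, and adjusted p = 0.054 with an estimated correlation), and unfolded protein response genes in 1 of 17 (median 0.03, adjusted p = 0.015, and adjusted p = 0.05 with an estimated correlation, which does not pass). At 24 h NRF2 genes rose in 4 of 14, 5 adjusted over the list alone (median 0.16, adjusted p = 0.0054, and adjusted p = 0.09 with an estimated correlation), and lysosome genes in 3 of 25 (median 0.09, adjusted p = 0.0039, and adjusted p = 0.36 with an estimated correlation).

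Genes called for Helicon 4-neg against DMSO were few at 6 h and many at 48 h. At 1 µM and 6 h limma called 4, named after their values were seen: STT3A rose by 0.25, while PACSIN3 fell by 0.41, SURF6 by 0.38 and IGFBP2 by 0.20. At an unadjusted p of 0.05 limma had 1608 genes there, edgeR called 0, and centring gave 3 higher and 2 lower. The count became 0 without Helicon 4-neg replicate 1 (1179 unadjusted), 1 without its replicate 2, 20 without its replicate 3, 0 without DMSO replicate 1 (1673 unadjusted) and 65 without DMSO replicate 3. At 1 µM and 24 h limma called 0 genes, with 676 at an unadjusted p of 0.05, and edgeR called 0. At 3 µM and 6 h 102 rose and 126 fell; the 228 became 1 and 39 without Helicon 4-neg replicates 1 and 3 and 104 without DMSO replicate 2. At 3 µM and 24 h 57 rose and 255 fell; the 312 became 153, 103 and 26 without Helicon 4-neg replicates 1, 2 and 3, and 57, 71 and 125 without DMSO replicates 1, 2 and 3.

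At 10 µM Helicon 4-neg gave 19 higher and 15 lower at 6 h, 21 and 10 after centring. The 34 became 10, 12 and 19 without Helicon 4-neg replicates 1, 2 and 3, and 18 without DMSO replicate 1. At 24 h 733 rose and 814 fell, 931 and 606 after centring, and 5 changed at least 2-fold: CENPF, TPR, APC and, named after their values were seen, CENPE (-1.29) and GOLGA4 (-1.32), all longer than at least 86.7% of the genes tested. The 1547 became 630, 740 and 978 without Helicon 4-neg replicates 1, 2 and 3, and 372, 999 and 815 without DMSO replicates 1, 2 and 3. At 48 h 1403 rose and 1152 fell, and 3 changed at least 2-fold, ID3, RSRP1 and ID1 (-1.01). The 2555 became 1343 and 1494 without Helicon 4-neg replicates 2 and 3, and 1198 and 1175 without DMSO replicates 2 and 3. At 1 µM and 48 h 1892 rose and 1389 fell, a total of 3281 that became 1466 without Helicon 4-neg replicate 1 and 2020 and 1794 without DMSO replicates 2 and 3. That replicate 1 stood apart from replicates 2 and 3 (chi-square per gene 25.0 and 29.6, beside 2.21 between those). At 3 µM and 48 h 2133 rose and 1682 fell, 1558 and 2193 after centring. The total of 3815 became 1968 without Helicon 4-neg replicate 3 and 2463 and 2382 without DMSO replicates 2 and 3. Its replicate 3 stood apart from replicates 1 and 2 as well (23.5 and 29.1, beside 5.62).

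At matched dose and time the compounds were compared directly, Helicon 4 against Helicon 4-neg. At 10 µM AXIN2 differed by -1.45 at 6 h (95% interval -1.55 to -1.36, adjusted p = 2.1e-17), -1.37 at 24 h (-1.47 to -1.28) and -1.83 at 48 h (-1.94 to -1.71). NKD1 differed by -1.36 (-1.49 to -1.22), -1.74 (-1.93 to -1.54) and -1.72 (-1.86 to -1.57), and TNFRSF19 by -1.87 at 6 h (-1.96 to -1.77) and -3.22 at 48 h (-3.42 to -3.02). MYC differed by -0.27 at 6 h (-0.36 to -0.18), -0.15 at 24 h (-0.26 to -0.04) and 0.19 at 48 h (0.08 to 0.29). Its 24 h call was lost without Helicon 4 replicate 2 (-0.11) or 3 (-0.14) and without Helicon 4-neg replicate 3 (-0.13). CTNNB1 was higher with Helicon 4 by 0.25 at 6 h (0.18 to 0.32) and 0.30 at 48 h (0.19 to 0.42). LGR5 differed by -0.43 at 24 h (-0.72 to -0.14), lost without Helicon 4 replicate 3 (-0.36) or Helicon 4-neg replicate 2 (-0.37), and by -0.27 at 48 h (-0.52 to -0.03, adjusted p = 0.056), which passed without Helicon 4-neg replicate 2 (-0.33) and after centring (-0.31). TCF7L2 differed by 0.66 at 24 h (0.27 to 1.05, lost without Helicon 4 replicate 1, 0.37) and 0.40 at 48 h (0.16 to 0.64). At 6 h KREMEN1 (-0.11, interval -0.21 to -0.01, adjusted p = 0.21), TCF7L2 (-0.03, interval -0.31 to 0.24, adjusted p = 0.93) and LGR5 (-0.22, interval -0.43 to 0, adjusted p = 0.24) did not pass after adjustment, though the unadjusted interval of KREMEN1 leaves out 0.

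At lower doses the compounds differed less at 6 h. At 1 µM limma called none of the 17 panel genes at 6 h: AXIN2 had 0.10 (0.01 to 0.19, adjusted p = 0.32), NKD1 -0.12 (-0.26 to 0.01, adjusted p = 0.41) and TNFRSF19 0.07 (-0.03 to 0.17, adjusted p = 0.54). At 3 µM and 6 h NKD1 differed by -0.69 (-0.83 to -0.56), SP5 by -0.82 (-1.03 to -0.60), DKK1 by -0.94 (-1.29 to -0.60), TNFRSF19 by -0.39 (-0.49 to -0.29) and AXIN2 by -0.27 (-0.36 to -0.18). By 24 h 1 µM was enough for a difference of -0.89 in AXIN2 (-0.99 to -0.80) and -1.75 in NKD1 (-1.94 to -1.55), and at 48 h these were -1.08 (-1.19 to -0.97) and -1.84 (-1.98 to -1.69).

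Among the largest differences between the compounds at 10 µM and 6 h were ID3 (1.40, SE 0.066, adjusted p = 8.6e-14), CCNG2 (0.92), INHBB (0.79) and TFEB (0.69), higher with Helicon 4, and IRX5 (-1.72), MEDAG (-1.70) and OXR1 (-1.66), lower. At 24 h BMF (3.16), EDIL3 (2.63), TP53INP2 (2.61) and TMCC3 (2.59) were higher, and WIF1 (-2.95), HDC (-2.90), TNFRSF19 (-2.56) and C9orf3 (-2.38) lower. At 48 h TMSB4X (3.45), BMF (3.38), CTNNA2 (3.33) and HIST1H2AC (3.18) were higher, and WIF1 (-3.47), MEP1B (-3.43) and HDC (-3.37) lower. Cholesterol synthesis genes were lower with Helicon 4 than with Helicon 4-neg in 21 of 24 at 24 h (median -0.54, adjusted p = 2.2e-10, and adjusted p = 0.039 with an estimated correlation) and 21 of 24 at 48 h (median -0.85, adjusted p = 7.7e-14, and adjusted p = 0.0088 with an estimated correlation). SQLE differed by -1.20 at 48 h.

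Wnt feedback regulators were lower with Helicon 4 in 10 of 11 at 6 h, 11 adjusted over the list alone (median -1.21, adjusted p = 1.4e-32, and adjusted p = 2.2e-05 with an estimated correlation), 10 of 11 at 24 h with 1 higher (median -1.74, adjusted p = 7.4e-09, and adjusted p = 0.0025 with an estimated correlation) and 11 of 12 at 48 h with 1 higher (median -1.88, adjusted p = 3.6e-10, and adjusted p = 2e-04 with an estimated correlation). Wnt targets, which include these regulators, were lower in 22 of 42, 25 of 43 and 23 of 44 and higher in 1, 11 and 10. Adjusted over the list alone 24, 25 and 24 were lower and 2, 11 and 10 higher (adjusted p = 5.4e-27, 0.00057 and 0.00022, and adjusted p = 0.00051, 0.11 and 0.012 with an estimated correlation). S phase genes were lower in 30 of 30 at 24 h (adjusted p = 4.1e-19, and adjusted p = 0.0011 with an estimated correlation) and G2/M genes in 31 of 32 at 48 h, 32 adjusted over the list alone (adjusted p = 3.4e-16, and adjusted p = 0.00077 with an estimated correlation). MYC-responsive genes were lower in 30 of 32 at 24 h and 29 of 32 at 48 h, the latter 30 adjusted over the list alone (adjusted p = 9.9e-14 and 2.3e-09, and adjusted p = 0.0011 and 0.00049 with an estimated correlation). Histone genes were higher in 8 of 8 at 24 h and 8 of 9 at 48 h (adjusted p = 2.2e-06 and 4.2e-06, and adjusted p = 0.0011 and 0.0061 with an estimated correlation). ATF4 genes at 48 h were lower in 15 of 24 and higher in 7 (adjusted p = 0.04, and adjusted p = 0.048 with an estimated correlation), with DDIT4, an inhibitor of mTORC1 signalling, higher by 1.87.

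Of the lists that rose with Helicon 4 at 6 h, some also separated it from Helicon 4-neg. Heat shock genes were higher with Helicon 4 in 6 of 14, 10 adjusted over the list alone (median 0.19, adjusted p = 2.1e-08, and adjusted p = 0.018 with an estimated correlation). Cholesterol synthesis genes were higher in 7 of 24 at 6 h, 12 adjusted over the list alone (median 0.09, adjusted p = 5.9e-06, and adjusted p = 0.039 with an estimated correlation), and S phase genes in 4 of 30 with 1 lower (median 0.07, adjusted p = 0.0021, and adjusted p = 0.021 with an estimated correlation). ATF4 genes (4 of 23 higher, 2 lower, adjusted p = 0.33) and NRF2 genes (2 of 14 higher, 1 lower, adjusted p = 0.18) did not pass at 6 h. At 48 h unfolded protein response genes were lower in 13 of 17 with 1 higher, 14 and 1 adjusted over the list alone (adjusted p = 6e-06, and adjusted p = 0.0061 with an estimated correlation), and lysosome genes higher in 16 of 25 with 4 lower (adjusted p = 0.00081, and adjusted p = 0.0091 with an estimated correlation).

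**Figure D4:**
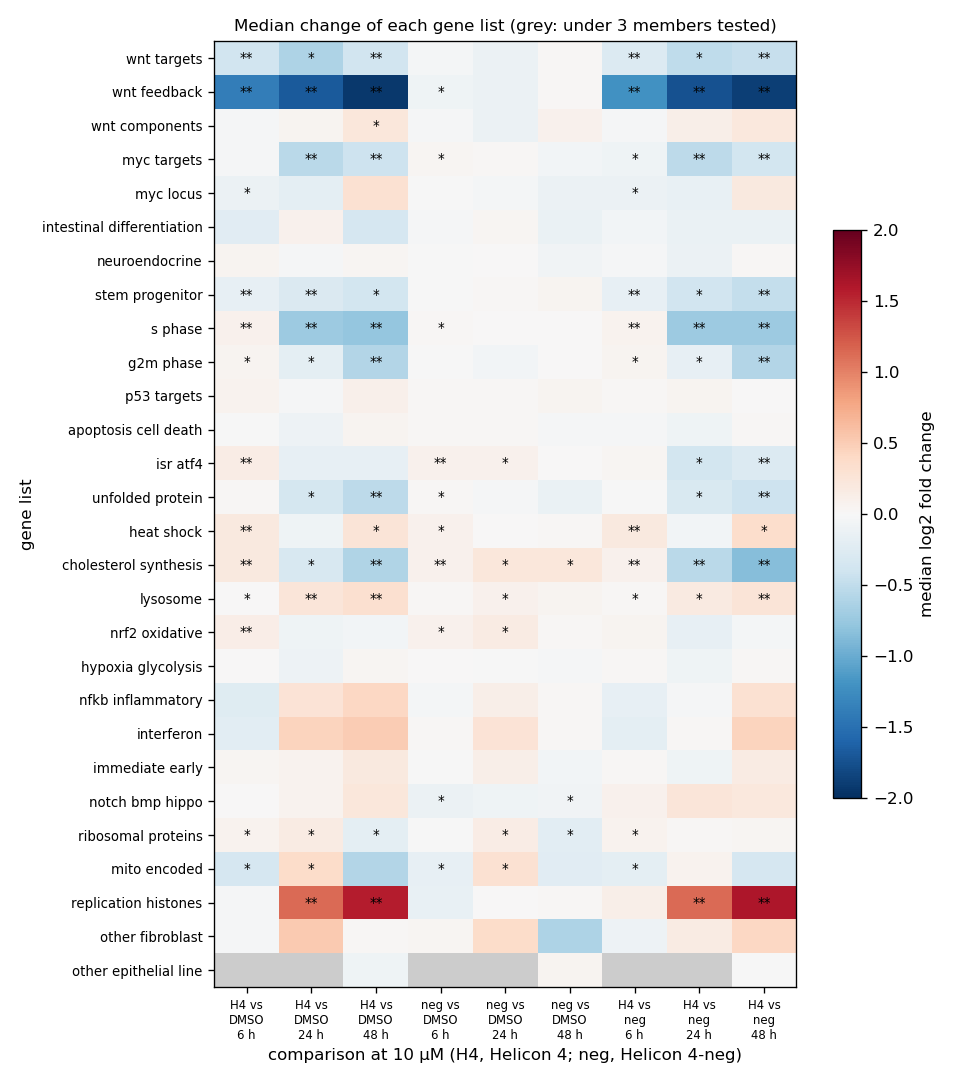
Median log2 fold change (colour) of 28 gene lists (vertical axis) in the 9 comparisons at 10 µM (horizontal axis), where 1 star marks a list called by camera, 2 stars a list called also with an estimated correlation, and grey fewer than 3 members tested. Wnt feedback regulators had medians of -1.39, -1.68 and -1.93 under Helicon 4 against DMSO at 6, 24 and 48 h, and no called list changed the sign of its median after median centring.

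The direct contrast of the compounds at 10 µM called 355 genes higher and 745 lower with Helicon 4 at 6 h (448 and 544 after centring), 3314 and 3644 at 24 h, and 3603 and 3640 at 48 h, with 34, 393 and 704 changed at least 2-fold. The 1100 at 6 h became 726 without Helicon 4 replicate 2 and 705 without Helicon 4-neg replicate 3. At 1 µM and 6 h 8 genes were called, named after their values were seen: RFK was higher (0.19), and NRARP (-0.36), RNF26 (-0.29), LAMP1 (-0.21), EID2 (-0.35), FBLN1 (-0.22), GRINA (-0.26) and KCTD7 (-0.40) were lower with Helicon 4. There, edgeR called 8 and centring gave 0 higher and 4 lower. The limma count became 0, 0 and 68 without Helicon 4 replicates 1, 2 and 3, and 0, 1 and 0 without Helicon 4-neg replicates 1, 2 and 3. The unadjusted counts behind these 0 values were 1504, 1068, 1451 and 1136. At 3 µM and 6 h 62 were higher and 152 lower, 75 and 114 after centring. The 214 became 129, 87 and 132 without Helicon 4 replicates 1, 2 and 3, and 96, 103 and 97 without Helicon 4-neg replicates 1, 2 and 3. At 1 µM and 24 h 1509 were higher and 1863 lower (1987 and 1370 after centring), and the 3372 became 2025 without Helicon 4 replicate 1. At 3 µM 2596 and 3073 were called at 24 h and 3496 and 3579 at 48 h, and at 1 µM 2127 and 2711 at 48 h.

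Genes called against DMSO with each compound at 10 µM overlapped. At 48 h 837 genes were higher and 806 lower with each compound, where independent lists would share 437 and 330, and 332 were called in opposite directions. At 24 h 252 were higher and 445 lower (184 and 225 for independent lists, 285 opposite), and at 6 h 13 and 9 (1.01 and 1.26, 2 opposite). The compounds shared 3 DMSO libraries, which cannot be split into sets of 2, so these controls can give part of the shared calls. Across genes, not independent replicates, the 2 sets of fold changes correlated by 0.48, 0.22 and 0.30 at 6, 24 and 48 h. In 100 simulated draws of unchanged groups against these controls the values were 0.50, 0.48 and 0.50. Their covariance was 0.012, 0.017 and 0.031, beside 0.0074, 0.0071 and 0.0078 in these draws, where controls alone gave 0 shared calls.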

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

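Tests chosen only after results were seen were the tests of the library-order pattern, the library-order term and the removal of the length and GC trend in the counts, the regrouping with treatment and time effects removed first, and the leave-one-out and other alternatives for the differences between times. Of 18 Wnt panel genes, 11 met the criterion that the effect of Helicon 4 10 µM against DMSO differed between 48 and 6 h, by an interaction term of a limma model with 3 libraries per group.

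WIF1 had -0.31 at 6 h and -3.39 at 48 h, a difference of -3.08 (SE 0.12, adjusted p = 7.6e-27). NOTUM differed by -2.47 (SE 0.083, adjusted p = 2.9e-30), ASCL2 by -1.56 (SE 0.13, adjusted p = 2.4e-14), APCDD1 by -1.23 (SE 0.064, adjusted p = 2.7e-22) and TNFRSF19 by -1.12 (SE 0.1, adjusted p = 3e-13). SP5 differed by -0.76 (SE 0.16, adjusted p = 9e-05) and CCND1 by -0.52 (SE 0.13, adjusted p = 0.00049). MYC differed by 0.58 (SE 0.07, adjusted p = 6.5e-10), from -0.27 at 6 h to 0.32 at 48 h, and KREMEN1 by 0.43 (SE 0.078, adjusted p = 6.6e-06), from -0.19 to 0.25. CTNNB1 differed by 0.23 (SE 0.058, adjusted p = 0.00067), a call lost after median centring (0.12). AXIN2 differed by -0.19 (SE 0.07, adjusted p = 0.019), a call lost without Helicon 4 6 h replicate 3 (-0.15), Helicon 4 48 h replicate 2 (-0.17) or DMSO 48 h replicate 1 (-0.14). DKK4 (-0.33, adjusted p = 0.071) did not pass, and passed after centring (-0.44), with edgeR and without DMSO 6 h replicate 3 (-0.39).

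Regrouping the libraries among treatments within each time gave as many genes as the real split of the time differences in several cases. For 24 against 6 h 6 of 100 splits gave as many as the real 5317, with 6033 as the highest other, for 48 against 24 h 15 of 100 (real 4720, highest other 8910), and for the compounds from 6 to 48 h 9 of 100 (real 5599, highest other 6288), so that chance is not excluded by this count. For 48 against 6 h 2 of 100 splits gave as many (real 6802, highest other 7095), a share under 0.05, but the criterion written beforehand also asked that no other split call more genes, and chance is not taken as excluded there either. Regroupings that keep 1 time's arms whole recount its treatment effect, so these counts cannot test chance. With the effects of treatment and time removed first, a test chosen later, 1 of 100 splits, the real one, was as large in each case. The highest others were 3118, 2780, 3316 and 4513 in the order given. Removing these effects leaves the real difference whole and shrinks the other regroupings in part, which favours the real split. Chance is therefore not taken as excluded by this test.

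At 48 h 2555 genes were called for Helicon 4-neg 10 µM against DMSO, 3 changed at least 2-fold. With each library's trend on gene length and GC content removed, 0.824 of that number were called (range 0.763 to 0.86 over leaving out each library), which argues against that trend as the whole cause. With the library-order term the ratio was 1.27 (0.989 to 2.13). Both groups held the same mix of libraries by label order, so the ratio cannot test the order pattern. Of 1405 genes called in one direction at all 3 doses, 42.1% changed more at 10 than at 1 µM (28.8 to 55.8). Their median absolute log2 change was 0.282 at 1 µM and 0.271 at 10 µM. By the prediction written beforehand that share argued against an effect that grows with dose. The range spans the bound of the prediction, a criterion added later, so such an effect stays open. The share passed that bound only without a 10 µM library (53.2, 55.8 and 55.7%). Libraries stood apart from their group at the other doses, Helicon 4-neg 1 µM replicate 1 and 3 µM replicate 3, and the share was 43.5% and 41.5% without them. A difference between the DMSO and Helicon 4-neg samples other than the compound was not tested.

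Helicon 4 1 µM at 6 h had 1655 genes called against DMSO and 8 against Helicon 4-neg 1 µM. With the length and GC trend removed, 0.574 of the former were called (0.352 to 0.731). By the prediction written beforehand a value at or above 0.5 argued against the trend as the cause, but the range over libraries spans that bound, a criterion added after the value was seen, and the trend stays open. The library-order term gave 1.07 (0.968 to 1.23). Here too both groups held the same mix of libraries by label order, so this ratio cannot test the order pattern. Of the called genes 71.2% (66.9 to 76.6) lay on the same side in Helicon 4 against Helicon 4-neg at 10 µM, beside 55.9% of genes not called, a share that a weaker form of the 10 µM effect would give. For most of these genes it is not shown, since 150 of 1655 were called in the same direction in that contrast, and of the feedback regulators at 1 µM against DMSO AXIN2 had 0.02 (adjusted p = 0.81) while NKD1 fell by 0.22 (adjusted p = 0.032), lost without Helicon 4 replicate 1 (-0.16) or 2 (-0.23) or DMSO replicate 2 (-0.16).

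The alternation of CXCL10, CXCL8 and GFAP along the label order held within 21 of 21 groups, which argues against treatment, dose or time as its cause. Of 17 astrocyte markers, listed after GFAP, EDNRB and GPM6A had been seen and without these, 10 differed between the 31 and 32 libraries, 58.8% beside 4.94% of other genes (one-sided Fisher p = 1.3e-09), 8 of them higher in the 32, such as AQP4 (4.05 against 0.845) and NTRK2 (5.78 against 2.21), and TNC and SPARC higher in the 31. Reads from astrocyte-like cells are a candidate source of part of the pattern, but GJA1 (133 and 130), NDRG2 (51.1 and 51.1) and SLC1A3 (56.7 and 55.8) were high in all libraries and did not differ, so that no cell type is shown. Over the 31 libraries the slope of log CXCL10 on log depth was -0.58 (95% interval -0.97 to -0.18), and those of CXCL8 (-0.70, -1.13 to -0.26) and CCL2 (-0.46, -0.84 to -0.08) also lay below 0, which argues against foreign RNA at a fixed share, with a slope of 0. A fixed number of foreign reads, with a slope of -1, stays open, since the interval of CXCL8 includes -1 while those of CXCL10 and CCL2 do not. What the source was stays open, and beyond the groups and the astrocyte markers no biological explanation was tested.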

How the results depend on the processing

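Alternatives chosen after the data were seen were edgeR on recovered reads, the library-order term, the length and GC correction, and those for the differences between times, leave-one-out included. The DESeq2 test and its size factors were planned for raw counts only and were not run, since the values are not raw counts. Of 568 named gene results, 489 kept their call and direction under the alternatives run on all of them, and none reversed. Length and GC was run on named genes for Helicon 4-neg 10 µM against DMSO at 24 h only, where KREMEN1 (-0.16, adjusted p = 0.074) became called (-0.11, adjusted p = 0.036). Of counts of genes, a pseudocount of 0.1 left 33 of 33 within 1.5 times the first value, edgeR 36 of 37, median centring 36 of 37, no filter on low values 36 of 37, the library-order term 34 of 37, robust empirical Bayes 31 of 33, 1 fit of all 63 libraries 30 of 33, length and GC 29 of 33, and leaving out 1 library did so 191 times and not 73 times. Of 92 list calls in 246 tests, 45 were lost with an estimated correlation and 5 with fry, which added 45. Where a count or call moved, the cause was not tested; leaving out a library also leaves fewer samples. Depth limits genes near 0, such as DKK4.

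Helicon 4 1 µM against DMSO at 6 h (1655 genes) gave 831 in 1 fit of all 63 libraries and 950 with length and GC. Helicon 4-neg 1 µM at 6 h (4) gave 7 with robust empirical Bayes, 0 with no filter, 7 in 1 fit of all 63 libraries, 0 with edgeR, 34 with the library-order term and 55 with length and GC; limma had 1608 there at an unadjusted p of 0.05. Helicon 4-neg 3 µM gave 354 with length and GC at 6 h (228) and 581 in 1 fit of all 63 libraries at 24 h (312). Helicon 4 against Helicon 4-neg 1 µM at 6 h (8) gave 25 with robust empirical Bayes, 4 with centring, 0 with the library-order term and 18 with length and GC; 1825 passed an unadjusted p of 0.05 in limma and edgeR called 8. The Helicon 4-neg slope at 48 h (302) gave 944 with the library-order term.

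With the replicate number as a block, Helicon 4-neg 1 µM at 6 h gave 0 in limma (1608 at an unadjusted p of 0.05 without the block, edgeR 0), Helicon 4 against Helicon 4-neg 1 µM at 6 h gave 0 (1825 without the block, edgeR 8), and the Helicon 4-neg slope at 48 h gave 160. The block moved no list call in 246 tests, and the replicate numbers are not known to mark a shared culture or day.

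Wnt feedback under Helicon 4-neg at 6 h had adjusted p = 0.057 with an estimated correlation, and at 24 h 0.037 with fry. Wnt targets at 24 h had 0.096 for Helicon 4 against DMSO and 0.11 against Helicon 4-neg with an estimated correlation. Immediate-early genes at 24 h reversed direction with fry, with adjusted p = 0.0062 against DMSO and 0.00042 against Helicon 4-neg. Lists called with the preset correlation, an estimated correlation and fry were 13, 8 and 15 for Helicon 4 against DMSO at 6 h, 12, 6 and 19 at 24 h, and 13, 9 and 20 at 48 h. For Helicon 4-neg they were 10, 2 and 10, then 6, 0 and 7, then 3, 0 and 8, and for the compounds 12, 6 and 14, then 11, 5 and 19, then 12, 11 and 22.

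Leaving out each library in turn (2 libraries then stand for that group), counts for Helicon 4 against DMSO at 1, 3 and 10 µM ranged from 209 to 2460, 446 to 1686 and 1170 to 2174 at 6 h, 1605 to 2550, 5161 to 5911 and 6270 to 7008 at 24 h, and 4531 to 5146, 7306 to 7580 and 7399 to 7704 at 48 h. For Helicon 4-neg against DMSO they ranged from 0 to 65, 1 to 336 and 10 to 45 at 6 h, 0 to 0 (378 to 747 at an unadjusted p of 0.05), 26 to 153 and 372 to 999 at 24 h, and 1466 to 3634, 1968 to 4072 and 1175 to 2710 at 48 h. For the compounds they ranged from 0 to 68, 87 to 132 and 705 to 844 at 6 h, 2025 to 3612, 4899 to 5301 and 6303 to 6889 at 24 h, and 4064 to 4548, 6309 to 6817 and 6515 to 6763 at 48 h. Slopes of Helicon 4 ranged from 689 to 1145, 3958 to 4968 and 3159 to 4182, and those of Helicon 4-neg from 3 to 11, 852 to 2532 and 72 to 444. Differences between times ranged from 4879 to 5136 (24 against 6 h), 6344 to 6666 (48 against 6 h), 4113 to 4854 (48 against 24 h) and 5151 to 5323 (compounds, 48 against 6 h).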

Other observations

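Of the tests here, the edgeR counts, the library-order term, the comparison of splits with the library order and the depth relations were chosen after the data were seen, and the regroupings were not.

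DDIT4, an inhibitor of mTORC1 signalling, had levels of 39.2 ± 1.6 with DMSO, 126 ± 5.1 with Helicon 4 10 µM and 34.1 ± 3.9 with Helicon 4-neg 10 µM at 48 h (SD, n = 3). ID2, which BMP signalling induces, had 15.5 ± 1.3, 25.7 ± 1.3 and 8.2 ± 1.3. CCAT2, a noncoding RNA of the MYC locus (ENSG00000280997, chromosome 8, 127400399 to 127402150), had 78.7 ± 4.3, 24.4 ± 1.4 and 90 ± 3.9, while MYC had 2640 ± 160, 3280 ± 88 and 2880 ± 40.

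Splits of the 6 libraries of each pair of groups number 10, so that their share is never under 0.1. For Helicon 4 against DMSO at 1, 3 and 10 µM, 1 of 10 splits gave as many genes as the real 1655, 1197 and 1791 at 6 h (highest others 3, 61 and 0), 2501, 5970 and 6968 at 24 h (17, 0 and 0), and 5513, 7983 and 8061 at 48 h (0, 3 and 0). For Helicon 4-neg against DMSO the real values were 4, 228 and 34 at 6 h, with highest others 0, 286 and 0, and 2 of 10 splits as large at 3 µM. At 24 h they were 0, 312 and 1547 (0, 0 and 65), with 10 of 10 as large at 1 µM, where limma called 0 genes, 676 passed an unadjusted p of 0.05 and edgeR called 0. At 48 h they were 3281, 3815 and 2555 (0, 43 and 0). For Helicon 4 against Helicon 4-neg they were 8, 214 and 1100 at 6 h (101, 0 and 0), with 2 of 10 as large at 1 µM, 3372, 5669 and 6958 at 24 h (0, 0 and 0), and 4838, 7075 and 7243 at 48 h (0, 0 and 38). The splits with 101, 65, 43, 38, 61 and 3 (the last for Helicon 4 3 µM at 48 h) follow the library order, and the 101 against a real 8 point to that structure of the libraries; with the library-order term this comparison called 0 genes (limma).

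For the dose slopes of Helicon 4, 1 of 100 splits gave as many genes as the real 1134, 4737 and 4213 at 6, 24 and 48 h (highest others 734, 4059 and 3228). Chance is excluded by the criterion written beforehand, though without 1 library the real counts fell as low as 689, 3958 and 3159. For Helicon 4-neg the real values were 8, 2612 and 302 with highest others 7, 1841 and 1009. The share was 1 of 100 splits at 6 and 24 h, which met that criterion, and 6 of 100 at 48 h, which did not. At 6 h the margin was 8 against 7, and without 1 library the real counts fell as low as 3 at 6 h and 852 at 24 h. Counts fell in this way for each compound, so chance is not taken as excluded for either compound at any time.

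Other chemokines were also lower in the deeper of the same 31 libraries. The slope of log level on log depth was -0.70 for CXCL8 (95% interval -1.13 to -0.26) and -0.46 for CCL2 (-0.84 to -0.08). Pearson r was -0.48 for CXCL10 (permutation p = 0.0058, adjusted p = 0.0087), -0.52 for CXCL8 (p = 0.0029, adjusted p = 0.0087) and -0.42 for CCL2 (p = 0.02, adjusted p = 0.02), and -0.39, -0.45 and -0.41 without the 2 libraries farthest in depth. Spearman rho was -0.57 (adjusted p = 0.0016), -0.59 (adjusted p = 0.0016) and -0.52 (adjusted p = 0.0035) in the same order.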
